A study of Mus musculus with 7501 samples.

How the data were processed

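The series measured RNA in 7501 wells of sorted cells from mouse colon, small intestine and spleen. Per the labels' protocols, gut tissue of C57BL/6J mice was incubated in 10 mM EDTA for 105 minutes and dissociated with TrypLE under the microscope until both single cells and multiplets were present. Small intestinal fractions were enriched for crypts by discarding early supernatants, per the labels' protocols. Live gut cells were sorted with 7AAD and an antibody to the epithelial marker CD326, Paneth cells were enriched with an antibody to CD24, and spleen cells were sorted with 7AAD alone. Cells went into 384-well or 96-well plates, and cDNA was made with a template switch and 21 cycles of amplification. Wells were selected on their cDNA profile before tagmentation with Nextera XT, and libraries were sequenced as 75 bp paired reads on a NextSeq 500, per the labels' protocols.

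The deposited values are raw read counts per gene symbol, 1 file per well, with no normalization by the authors found in the files. Reads were aligned with STAR, handled with Picard and counted with HTSeq on mm10 (GRCm38), per the submitters' processing notes, and the versions and the strand setting are not given in the sources used here. Each file has 24519 lines, of which 24421 name genes and 92 name spike-in RNAs, beside an EGFP transgene with 2 reads in 1 well and the summary lines of HTSeq. Genes took 41.2% of the reads, reads without a feature 11.8%, ambiguous reads 0.574%, the line for reads aligned to more than 1 place 45.6% and spike-ins 0.855%. That line equals the line for low alignment quality in every file, so what it counts is uncertain. If it holds reads from several places, genes in families of similar copies (alpha-defensins, Reg3, MHC) lose reads, and their levels are uncertain. No gene symbol named a mitochondrial transcript and no pair of files was identical. Coordinates are those of the GENCODE vM21 annotation on GRCm38. The counts carry no molecular identifiers, so intervals and floors cover counting error only.

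Wells with at least 50000 counts on genes and at least 500 genes with a count were kept, 7051 in all. Wells sorted as singlets were not filtered for doublets, because wells sorted as multiplets were fitted with the singlet profiles, and singlets fitted in the same way give the background. Kept singlets of both gut tissues were scaled to CPM, logged, reduced to 2000 variable genes and 30 principal components, joined to 15 neighbours and clustered with leidenalg 0.10.2 and igraph 0.11.9 at resolution 1.0 (seed 7). The 25 gut clusters and 16 spleen clusters were named from marker lists. A name needed at least 3 of a list's markers, and 50% of them, detected in 25% of the cells, a median log2 score of at least 0.5, and no stronger hit of another list among the 10 leading genes. Stem-like clusters were 1, 5, 7 and 18 (colon) with 15 and 17 (small intestine), cycling 6 and 22 (colon) with 10 and 11 (small intestine, with 2 colon cells in 11), goblet-like 3, 4 and 9 (colon, with 3 small intestinal cells in 9) with 12 (small intestine, with 2 colon cells), absorptive 8 (colon) with 13 and 19 (small intestine), and clusters 2, 14 and 16 stayed unnamed. Cluster 18, with 70 cells, was led by stress genes.

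Counts were summed over the kept wells of each tissue, sort label and age, and over the cells of each class with at least 10 cells. The labels name no animals, but wells of different ages must come from different animals, so age was the replicate; wells of the same age may hold several animals, and p-values measure only the spread between ages. Each comparison was fitted in edgeR 4.0.16 (R 4.3.3) with TMM, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05, using only the samples of the groups compared. CPM in the text are TMM-normalised means ± SD over ages, and log2 differences and SE come from edgeR. A fold against a group with no count was computed against a floor of 3 counts over that group, and a ratio against 1 to 3 counts is given with an exact 95% counting interval. The interaction was the difference of the multiplet to singlet contrast between the tissues, in 1 fit of the 4 gut groups.

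The genes named are, per direction, up to 12 with the largest log2 difference among those with an adjusted p under 0.05, at least 20 CPM in the higher group and no overlap between the samples of the groups, without predicted names, ribosomal protein genes or receptor segments, plus up to 3 members of each list; not every gene that the rule picks is reported. Lists were tested with camera on voom values (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, with adjustment over lists. There were 16 pathway lists and 13 gut marker lists, 29 in all, of which 22 to 28 had enough measured members to be tested in a comparison. The markers that named a class are not findings in that class. Values per age were compared with exact two-sided permutation or sign-flip tests (scipy 1.17.1).

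Each multiplet was fitted by non-negative least squares on the mean CPM profiles of the classes of its tissue, over the 50 leading genes per class, each scaled to its highest class mean and capped at 5 times it. A class counted as present at a weight share of 0.15 or more, and the unnamed clusters stayed in the reference as components of their own. Pairs were compared with 1000 shuffles within an age that kept the class totals and the classes per multiplet, as log2 of observed over expected with 0.5 added to each. Spleen multiplets and colon multiplets without an age were each shuffled as a whole. On singlets the fit found the cell's own class in 97.6% (small intestine), 98.0% (colon) and 93.8% (spleen). Of 2000 synthetic pairs of singlets it found both classes in 78.0%, 82.3% and 72.2%, and it called a further class in 34.2%, 39.6% and 47.8%.

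The edgeR steps were tested on simulated data with 200 changed genes. At a 4-fold change 62.1% were recovered in the comparison of all singlets (14657 genes), 47.0% in stem-like (12614), 45.5% in cycling (12281), 54.5% in goblet-like (12268), 25.8% in absorptive singlets (11538), 80.3% in colon multiplets (13248), 51.5% in small intestinal multiplets (13487) and 30.3% in the interaction (15005). At a 2-fold change the shares were 20.9%, 13.4%, 14.9%, 17.9%, 2.99%, 26.9%, 2.99% and 0 in the same order.

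Singlets and multiplets of the same age deviated together from their group means, with correlations across genes of 0.192, 0.180, 0.397, 0.223 and 0.195 in colon (ages 207, 269, 304, 453 and 492) and 0.417, 0.501 and 0.445 in small intestine (ages 304, 453 and 492). Each was the highest for its age, so age pairs the sort labels, and the fit with age as a block is given where it changes a call. The pairing was found in the data, because the labels do not say that wells of the same age share an animal.

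The tests, the marker and pathway lists, the well filter, the rule for named genes and most of the alternatives were chosen before the data were examined. The thresholds for naming clusters and the cap in the mixture fit were set with the data in view. Alternatives changed the normalization (size factors of DESeq2 1.42.0), the test (DESeq2), the filter on low counts, the well filter (100000 counts and 1500 genes, or 20000 and 300), the weight of wells, the block, the clustering resolution (0.5 and 1.5), the presence threshold (0.10 and 0.25), the genes per class (20 and 100), the scale and the reference of the mixture fit, and each age left out in turn. Other splits of the samples were counted, at most 100 per comparison. Spleen wells, and colon multiplets without an age, were left out of every test because nothing in the labels separates their animals. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.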

Results

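RNA was sequenced from single wells of sorted cells of the colon, the small intestine and the spleen of C57BL/6J mice, an inbred laboratory strain. Each well received a single cell (a singlet) or a clump of cells left attached after dissociation (a multiplet), as set by gates on the height and width of the forward scatter signal. The question behind the design is which cell types of the gut lining lie against each other, read from the mixed RNA of cells that stayed together. The values are read counts per gene, and 7051 of 7501 wells passed a minimum of 50000 counts and 500 detected genes. The kept wells were 1075 singlets and 414 multiplets of the small intestine, 2321 singlets and 1584 multiplets of the colon, and 1115 singlets and 542 multiplets of the spleen. Over all wells, total counts ran from 10148 to 2869444, with a median of 195626. The median was 156742 in small intestinal singlets, 200959 in small intestinal multiplets, 189886 in colon singlets and 171651 in colon multiplets.

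The replicate was the age of the animals in days, because the labels name no animals. Small intestinal singlets and multiplets came from ages 304, 453 and 492. Colon singlets came from ages 207, 269, 304, 359, 453 and 492, and colon multiplets from the same ages without 359. Counts summed over the kept wells of an age ranged from 9600444 in colon multiplets of age 453 to 172118307 in colon singlets of age 207. Another 1254 kept colon multiplets carry no age and entered no test, and neither did the spleen wells. Each of the 24 plates held 1 tissue only, so plate and tissue cannot be told apart in any comparison between the tissues.

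The first comparison asked how epithelial cells of the small intestine and of the colon differ, over all kept singlets summed by age (n = 3 and 6 ages). Hoxb13 and Gata4, transcription factors that mark position along the gut, did not overlap between the ages of the tissues. Hoxb13, a posterior homeobox factor on chromosome 11 (96194316 to 96197447, plus strand, GRCm38), had 283 ± 108 CPM (SD) in colon and 0.0870 ± 0.0449 in small intestine, a log2 difference of -11.66 (SE 0.65, edgeR adjusted p = 6.1e-06). Gata4, which sets jejunal identity (chromosome 14, 63198922 to 63271692, minus strand), had 97.0 ± 35.9 CPM in small intestine and 0.473 ± 0.893 in colon (log2 8.02, SE 1.33, adjusted p = 0.0024; log2 9.76 without colon age 453). Best2, a bicarbonate channel of colonic goblet cells, had 103 ± 55.9 CPM in colon and 0.0198 ± 0.0224 in small intestine.

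Of 15000 genes tested, 981 were higher in small intestine and 1310 lower (edgeR), 2291 in all and 1250 with age as a block. The genes with the largest differences had little or no RNA in the other tissue. Hsd17b6, a retinol and steroid dehydrogenase, had 22.6 ± 26.2 CPM in small intestine and no count in colon, so it was at least 3805-fold higher, the floor being 3 counts over the group (8.10 CPM and at least 1364-fold without small intestinal age 492). Gkn3, a gastrokine of small intestinal crypts, had 35.2 ± 32.1 CPM in small intestine against 1 count in colon, a ratio of 17779 (95% counting interval 3191 to 702220.0), or 8813 without small intestinal age 453. Apoa4, an apolipoprotein of lipid-absorbing cells, had 144 ± 191 CPM against 0.0549 ± 0.0711 (log2 11.20, SE 1.27, adjusted p = 0.00023), with 35.4 CPM and a log2 of 9.15 without small intestinal age 492 and a log2 of 12.43 without colon age 359. The other 9 named genes higher in small intestine were Slc5a11, Ugt2a3, Cyp2e1, Defa26, Bcl2l15, Fam20a, Reg3a, Habp2 and Apoc3. In colon, Fut9, a fucosyltransferase, had 39.5 ± 21.2 CPM against no count, at least 2652-fold higher, and Mira, a non-coding RNA of the Hox region, had 21.9 ± 5.95 CPM, at least 1474-fold higher. The other named colon genes were Nov, Foxd2, Tmprss13, Hoxa7, Hoxa11os, Lpo, Nxpe4 and Abo. Defa26 and Reg3a belong to families of near-identical copies, and reads of Hoxa11os may come from its antisense partner because the strand setting of the counting is not given in the sources used here.

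Gene lists fixed in advance were tested with camera, and 13 of the 27 lists with enough measured members passed over all singlets, of which 1 held with an estimated correlation. That list was the posterior transcription factors, with 9 of 9 genes lower in small intestine over all genes and 9 adjusted over the list alone (median log2 -5.09, camera adjusted p = 2.7e-08, and 0.020 with an estimated correlation). All 7 MHC class II genes, which present antigen to helper T cells, were higher in small intestine, and 7 adjusted over the list alone (median log2 5.36, camera adjusted p = 8.3e-09, adjusted p = 0.17 with an estimated correlation). Cd74, the invariant chain (chromosome 18, 60803848 to 60812652, plus strand), had 998 ± 429.7 CPM in small intestine and 24.3 ± 44.5 in colon (log2 5.36, SE 1.22, edgeR adjusted p = 0.013; log2 7.34 without colon age 304). In the lipid absorption list 11 of 14 genes were higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 2.6e-07, adjusted p = 0.23 with an estimated correlation). Mttp, which loads lipid onto lipoproteins, had 448 ± 325 CPM against 4.33 ± 1.88 (log2 6.70, SE 0.58, adjusted p = 4.2e-05; log2 6.03 without small intestinal age 492). The antimicrobial list had 11 of 14 genes higher and 1 lower, the same numbers adjusted over the list alone (camera adjusted p = 3.7e-06, adjusted p = 0.21 with an estimated correlation). Reg3g, a lectin that kills Gram-positive bacteria, had 936 ± 349 CPM against 64.7 ± 35.8 (log2 3.86, SE 0.55, adjusted p = 0.00091). The transport list for sugars, peptides and amino acids had 10 of 11 genes higher (11 adjusted over the list alone; camera adjusted p = 1.4e-06, adjusted p = 0.26 with an estimated correlation).

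Cell cycle genes were also higher in small intestinal singlets, 9 of 12 over all genes and 11 adjusted over the list alone (median log2 1.25, camera adjusted p = 4.8e-08, adjusted p = 0.17 with an estimated correlation). The cycling markers were the same 12 genes. Ccna2, a cyclin of S and G2 phase, had 314 ± 20.3 CPM against 134 ± 34.2 (log2 1.23, SE 0.21, adjusted p = 0.0031). Immediate early and heat shock genes were lower, 3 of 17 over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.49 with an estimated correlation), with Nr4a1 at 21.8 ± 11.8 CPM against 185 ± 123. Paneth markers had 10 of 12 genes higher (10 adjusted over the list alone; camera adjusted p = 1.9e-05, adjusted p = 0.38 with an estimated correlation) and small intestinal enterocyte markers 11 of 13 (12 adjusted over the list alone; camera adjusted p = 1.4e-06, adjusted p = 0.38 with an estimated correlation). The lists of anterior transcription factors (4 of 7 genes higher and 4 adjusted over the list alone, camera adjusted p = 9.3e-06), interferon genes (0.0056) and B cell markers (0.0031) were called as well, with adjusted p = 0.17, 0.49 and 0.17 with an estimated correlation, and the B list shares Cd74 with the MHC class II list. Goblet markers had 5 of 13 genes lower and 1 higher (7 and 1 adjusted over the list alone) and missed the threshold (camera adjusted p = 0.084). Agr2, a protein-folding enzyme of mucus cells, was lower in small intestine, at 598 ± 11.2 CPM against 1579 ± 464 (log2 -1.40, SE 0.25, adjusted p = 0.0036). Camera made no call for bile acid handling (adjusted p = 0.088), ion and water transport (0.18), stem markers (0.18), tuft markers (0.25), mucus (0.34), stromal markers (0.43), myeloid markers (0.44), junction and adhesion (0.46), niche ligands and Notch (0.51), colonocyte markers (0.67), enteroendocrine markers (0.70), lymphocyte markers (0.92) or Wnt and stem (0.98). The erythroid list had 1 measured member and the plasma cell list 2, too few to test. All singlets pool the cell classes in unlike shares, so the same comparison was made within classes. The clusters named stem-like, cycling, goblet-like and absorptive hardly mixed the tissues, with at most 3 cells of the other tissue in a cluster, so within a class separate clusters of the same name were compared.

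Stem-like singlets were compared to see which differences hold within the cells that renew the lining (n = 3 and 6 ages). Olfm4, a secreted glycoprotein of crypt base cells (chromosome 14, 79984081 to 80023139, plus strand), had 4860.0 ± 1193 CPM in small intestine and 0.483 ± 0.449 in colon (log2 13.80, SE 0.66, edgeR adjusted p = 4.9e-08). It is also 1 of the markers that named the stem-like clusters. Gkn3 (chromosome 6, 87383256 to 87388935, minus strand) had 109 ± 51.7 CPM in small intestine and no count in colon, at least 5169-fold higher. Slc14a1, a urea transporter, had 172 ± 35.9 CPM against 0.0648 ± 0.144 (log2 11.09, SE 0.72, adjusted p = 9.7e-07; log2 13.46 without colon age 304). Gata4 had 41.6 ± 11.2 CPM in small intestine against 1 count in colon, a ratio of 5928 (95% counting interval 1064 to 234150.0). In colon stem-like cells, Nxpe4, a secreted neurexophilin-like esterase (chromosome 9, 48162023 to 48400025, plus strand), had 147 ± 100.0 CPM and no count in small intestine, at least 1555-fold higher. Fut9 (chromosome 4, 25609332 to 25800244, minus strand) had 95.9 ± 56.3 CPM and was at least 1016-fold higher, and Hoxa11os (chromosome 6, 52244393 to 52249799, plus strand, a non-coding transcript) had 129 ± 58.7 CPM and was at least 1362-fold higher.

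**Figure D1:**
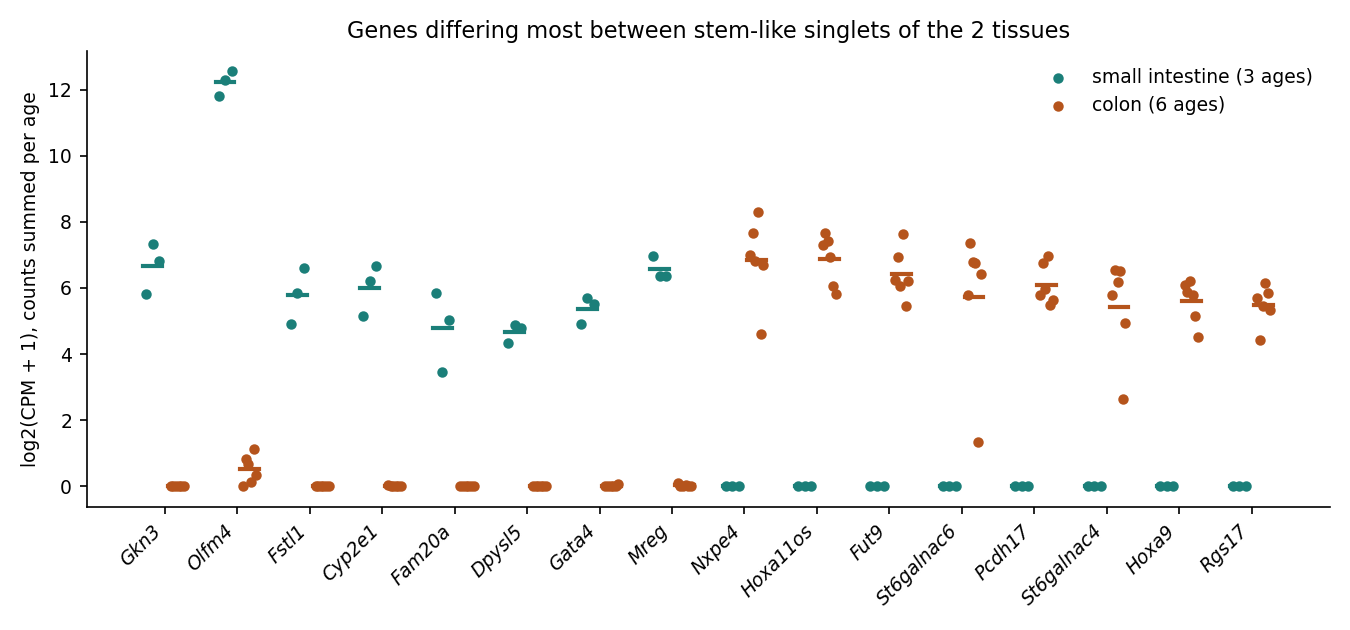
Each point is the log2(CPM + 1) of a gene in stem-like singlets of 1 age, for 8 genes higher in small intestine (teal, 3 ages) and 8 higher in colon (orange, 6 ages), and bars mark the mean of the log values. The small intestinal and colon ages do not overlap for any of the 16 genes, which the rule for named genes required. Means in the higher tissue run from 4860.0 CPM (Olfm4) to 24.7 CPM (Dpysl5), both in small intestine.

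Of 12895 genes tested in stem-like singlets, 298 were higher in small intestine and 536 lower (edgeR). The total of 834 depended on the fit, with 375 genes with age as a block, 416 over the shared ages without a block and 1471 in DESeq2. The other named genes higher in small intestine were Fstl1, Fam20a and Dpysl5, with no count in colon and bounds from at least 1172-fold (Dpysl5) to 2883-fold (Fstl1), and Cyp2e1, Mreg, Ugt2a3, Adrbk2 and Onecut2, with 1 to 13 counts in colon. Those higher in colon included the sialyltransferases St6galnac6 and St6galnac4, Pcdh17, Hoxa9, Rgs17, Foxd2, Lpo, Mfap3l and Arhgap20, each with no count in small intestine, with bounds from at least 339-fold (Arhgap20) to 918-fold (St6galnac6). Cd44, a hyaluronan receptor and Wnt target, had 222 ± 57.5 CPM in small intestine against 635 ± 146 in colon (log2 -1.52, SE 0.23, adjusted p = 0.0010). Camera called 14 of 23 lists and 8 held with an estimated correlation. MHC class II genes were higher in 5 of 7 over all genes and 7 adjusted over the list alone (median log2 5.44, camera adjusted p = 4e-13, and 0.047 with an estimated correlation), with Cd74 at 1420.0 ± 549.6 CPM against 25.4 ± 53.5 (log2 5.79, or 8.58 without colon age 304). Antimicrobial genes were higher in 8 of 13 (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.7e-11, and 0.014 with an estimated correlation), with Reg3g at 528 ± 252 CPM against 94.4 ± 38.5. Lipid absorption genes were higher in 6 of 11 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.8e-07, and 0.0091 with an estimated correlation), with Mttp at 114 ± 34.5 CPM against 4.88 ± 2.10. Posterior transcription factors were lower in 7 of 8 (8 adjusted over the list alone; camera adjusted p = 1.8e-08, and 0.0091 with an estimated correlation). The lists of Paneth markers, anterior transcription factors, enterocyte markers and nutrient transport also held, with adjusted p = 0.047, 0.033, 0.033 and 0.017. Calls for stem markers, interferon, the cell cycle (with the same genes as cycling markers), Wnt and immediate early genes were lost, with adjusted p = 0.21, 0.21, 0.31, 0.45 and 0.55 with an estimated correlation.

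Cycling singlets were compared in the same ages (n = 3 and 6), to see which differences hold among dividing cells. As the clusters are separate in each tissue, dividing goblet cells may be placed in unlike classes, which was not tested. Muc2, the gel-forming mucin (chromosome 7, 141690340 to 141754693, plus strand), had 775 ± 387 CPM in cycling colon cells and 4.83 ± 2.49 in small intestine (log2 -7.29, SE 0.92, edgeR adjusted p = 0.00027). Agr2 had 825 ± 304 CPM in colon against 57.8 ± 19.3 (log2 -3.83, SE 0.36, adjusted p = 2.2e-05). Sis, the brush border sucrase-isomaltase (chromosome 3, 72888557 to 72967863, minus strand), had 83.0 ± 31.1 CPM in cycling small intestinal cells against 3 counts in colon, a ratio of 2050.2 (95% counting interval 702 to 9942). Slc14a1 had 76.4 ± 50.4 CPM in small intestine and no count in colon, at least 1888-fold higher (1215-fold without small intestinal age 453). Hoxa10 (chromosome 6, 52231197 to 52240854, minus strand) had 85.7 ± 42.9 CPM in colon against 1 count in small intestine, a ratio of 6094 (95% counting interval 1094 to 240680.0).

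Of 12650 genes tested in cycling singlets, 281 were higher in small intestine and 589 lower (edgeR), 870 in all, with 520 without small intestinal age 304, 561 without age 492, 452 with age as a block, 535 over the shared ages without a block and 1358 in DESeq2. The other named genes higher in small intestine were Ugt2a3, Sfrp5, Bcl2l15, Gkn3, Cyp2e1, Enpep, Krt20, Abcg8, Fam20a and Pitx1. Those higher in colon were Nxpe2, at 86.2 ± 64.5 CPM and at least 2043-fold higher, Pcdh17, St6galnac4, Fut9, Mkx, Gna14, Vsig1, Foxd2, Capn2, Nxpe4 and Il1r1. Camera called 12 of 24 lists and 5 held with an estimated correlation. Enterocyte markers were higher in 6 of 12 (9 adjusted over the list alone; camera adjusted p = 1.7e-09, and 0.013 with an estimated correlation), lipid absorption in 8 of 14 with 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 4e-09, and 0.023), and antimicrobial genes in 5 of 13 with 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.00011, and 0.042). Posterior transcription factors were lower in 8 of 9 (9 adjusted over the list alone), with a median log2 of -6.52, or -5.00 with members at 0 counts set to their bound, and held at adjusted p = 0.023. Nutrient transport was higher in 1 of 7 genes (5 adjusted over the list alone) and held at adjusted p = 0.029. Goblet markers were lower in 9 of 13 (11 adjusted over the list alone; median log2 -4.29, camera adjusted p = 7e-07, adjusted p = 0.23 with an estimated correlation), and mucus genes in 4 of 10 with 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.0027, adjusted p = 0.36 with an estimated correlation). MHC class II genes were higher in 6 of 7 (7 adjusted over the list alone; camera adjusted p = 6e-07, adjusted p = 0.19 with an estimated correlation). Calls for anterior transcription factors, B markers, Paneth markers and immediate early genes were lost, with adjusted p = 0.061, 0.080, 0.23 and 0.59 with an estimated correlation.

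Goblet-like singlets were compared because the mucus of the tissues differs in thickness and make-up (n = 3 and 6 ages). Fcgbp, a protein that cross-links mucus (chromosome 7, 28071236 to 28120862, plus strand), had 11835 ± 852 CPM in small intestine and 2601 ± 987 in colon (log2 2.19, SE 0.26, edgeR adjusted p = 8.1e-05). Tff3, a trefoil peptide of mucosal repair, had 3341 ± 291 CPM against 665 ± 297 (log2 2.33, SE 0.29, adjusted p = 0.00014). Both are among the markers that named the goblet-like clusters. Mmp7, the protease that activates alpha-defensins, had 587 ± 171 CPM against 4.99 ± 2.88 (log2 6.91, SE 0.43, adjusted p = 3.7e-07). Mmp7 is also a Paneth marker, as are Lyz1, Habp2 and Defa24 in the next paragraph. Singlets were not filtered for doublets, and 6 of 1075 small intestinal singlets were called with both Paneth and goblet classes. Whether Paneth RNA in goblet-like wells contributed to the values of these genes was not tested. Best2 (chromosome 8, 85007202 to 85014531, minus strand) had 292 ± 95.7 CPM in colon against 1 count in small intestine, a ratio of 6304 (95% counting interval 1132 to 249000.0). Top2a, a topoisomerase of dividing cells, had 143 ± 32.2 CPM in small intestinal goblet-like cells and 8.97 ± 8.60 in colon (log2 3.97, SE 0.64, edgeR adjusted p = 0.00094, and log2 4.57 without colon age 359). Among cycling cells the goblet marker Muc2 was higher in colon. The line between cycling and goblet-like clusters may thus lie differently in each tissue, which was not tested.

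Of 12541 genes tested in goblet-like singlets, 622 were higher in small intestine and 858 lower (edgeR), 1480 in all and 745 with age as a block. Fam20a, a kinase-like protein, had 45.9 ± 4.52 CPM in small intestine and no count in colon, at least 2540.0-fold higher. Others higher in small intestine included Onecut2, Habp2, Serpina1b, Bcl2l15, Olfm4, Tm4sf4, Mreg, Defa24, H2-Aa and Defa6, of which Defa24, Defa6 and H2-Aa belong to families of similar genes. In colon, Hoxa11os had 186 ± 65.0 CPM and was at least 1341-fold higher, Anxa1, an anti-inflammatory annexin, had 86.6 ± 36.0 CPM and was at least 624-fold higher, and Abo, a blood group transferase, had 71.9 ± 16.5 CPM and was at least 517-fold higher. The others were Pla2g4c, Foxd2os, Cldn14, Chodl, Nxpe2, Tmprss13, Tspan33 and Cma1, and the doubt about the strand holds for Foxd2os as for Hoxa11os. Camera called 14 of 22 lists and 9 held with an estimated correlation. Antimicrobial genes were higher in 8 of 11 and lower in 2, with the same numbers adjusted over the list alone (camera adjusted p = 9e-12, and 0.0039 with an estimated correlation), and Lyz1, lysozyme, had 869 ± 381 CPM against 16.4 ± 20.8 (log2 5.78, or 6.69 without colon age 453). Cell cycle genes were higher in 7 of 12 (9 adjusted over the list alone; camera adjusted p = 5.5e-13, and 0.012 with an estimated correlation), as were the identical cycling markers. MHC class II genes were higher in 7 of 7 (7 adjusted over the list alone; camera adjusted p = 7.6e-12, and 0.024 with an estimated correlation). Posterior transcription factors were lower in 4 of 9 (6 adjusted over the list alone; median log2 -3.77, or -3.19 with members at 0 counts set to their bound) and held at adjusted p = 0.013. Lipid absorption, Paneth markers, enterocyte markers and anterior transcription factors held at adjusted p = 0.0082, 0.012, 0.012 and 0.013. Goblet markers went both ways, with 6 of 13 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.00020, adjusted p = 0.091 with an estimated correlation). Calls for nutrient transport, interferon, junction and mucus genes were lost, with adjusted p = 0.057, 0.091, 0.12 and 0.14 with an estimated correlation, and Cldn2, a pore-forming claudin, had 31.4 ± 11.8 CPM against 397 ± 169 in colon.

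Absorptive singlets, the enterocytes of the small intestine and the colonocytes of the colon, could be compared in 2 small intestinal and 3 colon ages. Enpep, a glutamyl aminopeptidase of the brush border (chromosome 3, 129269175 to 129332720, minus strand), had 812 ± 294 CPM in small intestine and no count in colon, at least 10073-fold higher. Slc2a2, the basolateral glucose and fructose carrier, had 238 ± 128 CPM and no count in colon, at least 2956-fold higher (1835-fold without small intestinal age 492). Slc6a14, an amino acid importer (chromosome X, 21714896 to 21742355, plus strand), had 1530.4 ± 185 CPM in colon against 1 count in small intestine, a ratio of 63927 (95% counting interval 11474 to 2525000.0). Aqp4, a water channel, had 1909 ± 573 CPM in colon and 13.2 ± 0.854 in small intestine (log2 -7.17, SE 0.36, edgeR adjusted p = 2.4e-05). Car1, a carbonic anhydrase (chromosome 3, 14766216 to 14808368, minus strand), had 3832 ± 981 CPM against 0.204 ± 0.134, but it is a marker that named the colonocyte clusters.

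Of 11865 genes tested in absorptive singlets, 514 were higher in small intestine and 627 lower (edgeR), 1141 in all, with 658 without small intestinal age 492 and 1966 in DESeq2. The other named genes higher in small intestine were Adh6a, at least 8127-fold, Creb3l3, Ggt1, Bcl2l15, Abcg8, Rragd and the enterocyte markers Lct, Anpep, Fabp1 and Treh. Those higher in colon were Anxa1, at 425 ± 48.9 CPM and at least 5918-fold, Cyp2c69, Lpl, Cwh43, Gna14, Prkacb, Fa2h, Slc8a1, Hoxa10 and Foxd2os, the last with the same doubt about its strand. Camera called 14 of 23 lists and none held with an estimated correlation, where adjusted p ran from 0.34 to 0.46. Nutrient transport genes were higher in 11 of 11 (11 adjusted over the list alone; median log2 12.31, or 9.34 with members at 0 counts set to their bound; camera adjusted p = 2.1e-08, adjusted p = 0.34 with an estimated correlation). MHC class II genes were higher in 6 of 7 (7 adjusted over the list alone; camera adjusted p = 8.2e-07, adjusted p = 0.34 with an estimated correlation), and lipid absorption genes in 11 of 14 (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.4e-06, adjusted p = 0.37 with an estimated correlation). Ion and water transport genes were lower in 4 of 10 and higher in 1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.37 with an estimated correlation), with Car2 at 7.63 ± 8.67 CPM against 3753 ± 605 in colon (log2 -8.90, or -8.09 and -11.33 without small intestinal age 304 and 492). Reg3g was again higher in small intestine, at 2318 ± 21.3 CPM against 145 ± 41.3 (log2 4.00, SE 0.26, adjusted p = 6.7e-05). The other called lists were anterior and posterior transcription factors, enterocyte and colonocyte markers, immediate early, antimicrobial, goblet, interferon and cell cycle genes. Enterocyte and colonocyte markers named these clusters, so their list calls follow from the naming and are not findings. The lipid absorption list shares Mttp with the enterocyte markers.

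Class shares asked whether the tissues differ in composition among sorted singlets (n = 3 and 6 ages). Cycling cells made up 29.1% ± 8.46 of small intestinal and 11.9% ± 4.09 of colon singlets, with every small intestinal age above every colon age (exact two-sided permutation p = 0.0119, the smallest that 84 splits give, adjusted p = 0.107 over 9 classes). Goblet-like cells were 12.8% ± 1.69 in small intestine and 31.3% ± 12.7 in colon (permutation p = 0.0833, adjusted p = 0.171). Stem-like cells were 19.6% ± 11.1 and 33.1% ± 7.46 (permutation p = 0.0476, adjusted p = 0.171). The stem-like difference of -13.5 points depended on the clustering: it was -29.2 at resolution 0.5, with every small intestinal age (0.889% to 14.6%) below every colon age (22.2% to 45.1%; adjusted p = 0.0536), and -7.42 at resolution 1.5 (adjusted p = 0.50). Absorptive cells were 19.03% ± 15.0 and 6.29% ± 5.14 (permutation p = 0.0952, adjusted p = 0.171). Paneth-like cells, the defensin-secreting cells of small intestinal crypts, were 2.12% ± 2.86 of small intestinal singlets and none of 2321 colon singlets (permutation p = 0.0833, adjusted p = 0.171). Lymphocytes, tuft-like, enteroendocrine-like and unnamed cells had permutation p from 0.333 to 0.857, adjusted p from 0.50 to 0.857. No class passed after adjustment, and the sort enriched Paneth cells with an anti-CD24 gate in wells that are not marked, and small intestinal fractions were enriched for crypts, so the shares are those of the sort and not of the tissue.

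**Figure D2:**
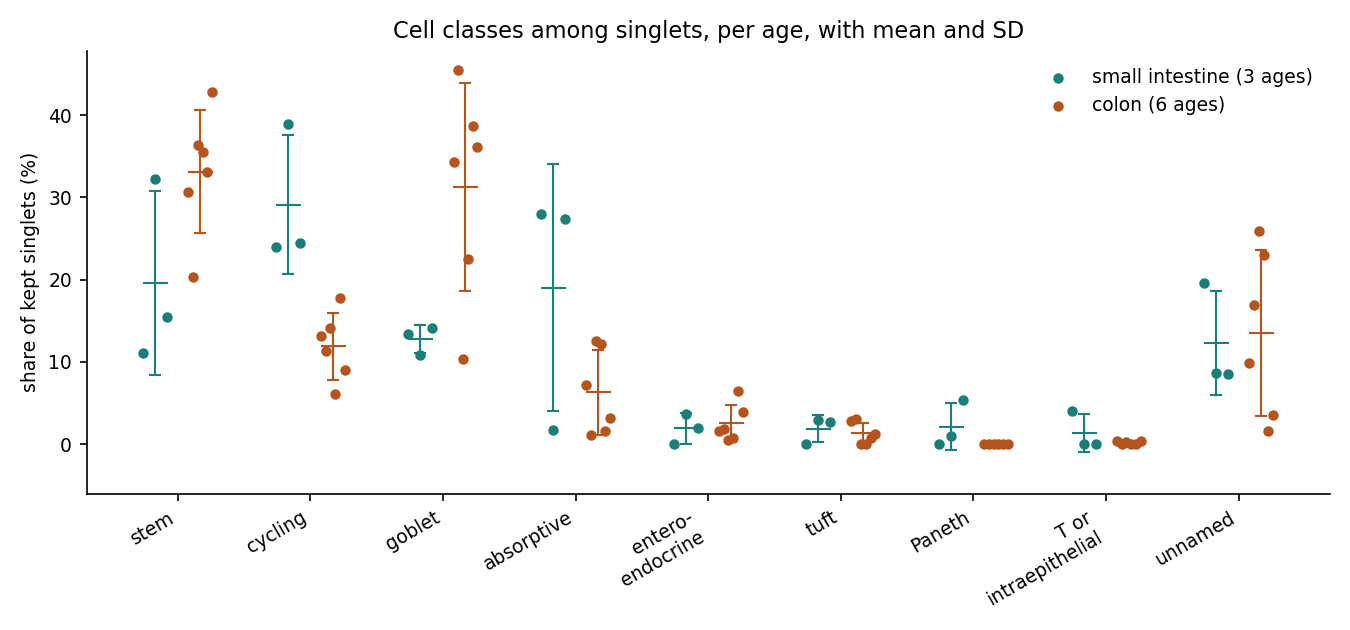
Each point is the percentage of kept singlets of 1 age in a cell class, with the mean ± SD over 3 small intestinal and 6 colon ages for 9 classes. Cycling cells, at a mean of 29.1% in small intestine and 11.9% in colon, are the class in which the ages of the tissues do not overlap.

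Genes detected per well were compared between sort gates, since attached cells of different types should bring more genes. Small intestinal multiplets had a median of 7002 ± 308 genes per well over 3 ages and singlets 4700.3 ± 77.0, 1.49-fold more, higher in 3 of 3 ages (exact two-sided permutation p = 0.10, the smallest that 20 splits give). Colon multiplets had 5519 ± 772 genes over 5 ages and singlets 4258 ± 502 over 6, 1.30-fold more, higher in 5 of 5 shared ages (exact permutation p = 0.0173 of 462 splits). Paired by age, the colon difference was 1215 genes (exact sign-flip p = 0.062, the smallest that 5 pairs give). With every well thinned to 50000 counts, colon multiplets still had 4921 ± 633 genes against 3827 ± 416 (exact permutation p = 0.00866). Counts on genes per spike-in count, a measure of RNA content, were 2.44-fold higher in small intestinal multiplets (exact permutation p = 0.10, n = 3 ages) and 1.83-fold higher in colon multiplets (exact permutation p = 0.154, higher in 4 of 5 ages). Within plates that held both gates, the fold ran from 2.13 to 3.44 on 5 small intestinal plates, from 1.04 to 2.39 on 6 colon plates and from 1.55 to 2.46 on 5 spleen plates.

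**Figure D3:**
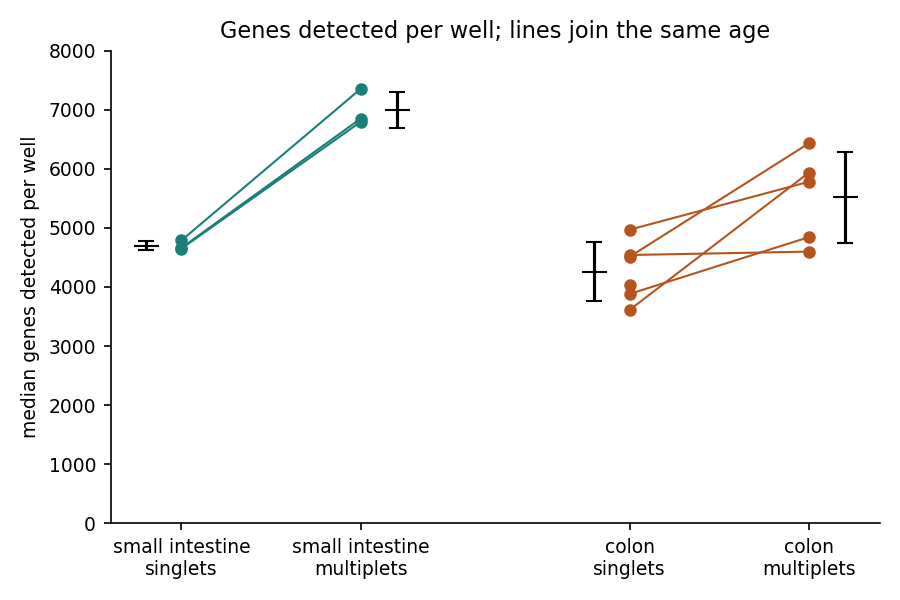
Each point is the median number of genes with a count per well in singlets or multiplets of 1 age, lines join the same age, and black marks the mean ± SD. Multiplets lie above singlets in all 3 small intestinal and all 5 shared colon ages, by little at colon age 207 (4598.5 against 4541 genes).

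Colon multiplets and singlets were compared gene by gene to find the classes that stay attached (n = 5 and 6 ages). Goblet markers had the highest median difference of the lists measured. Muc2 had 12193 ± 9423 CPM in multiplets and 3507 ± 2346 in singlets (log2 1.80, SE 0.56, edgeR p = 0.0063 and adjusted p = 0.69 over all genes). Clca1, a mucus-processing protease, had 2826 ± 1938 CPM against 922 ± 682 (log2 1.62, SE 0.52), and Ang4, an antimicrobial ribonuclease, 536 ± 364 against 145 ± 115 (log2 1.88, SE 0.56). No gene of 13526 passed in edgeR, where 931 had an unadjusted p under 0.05, and DESeq2 called 13. Goblet markers were higher as a list in 13 genes, none over all genes and 8 adjusted over the list alone (median log2 1.05, camera adjusted p = 3.8e-12, adjusted p = 0.28 with an estimated correlation). Mucus genes behaved alike, with none of 10 over all genes and 6 adjusted over the list alone (median log2 0.91, camera adjusted p = 1.4e-08, adjusted p = 0.28 with an estimated correlation). Paneth markers, Ang4 among them, were called higher (none of 7 over all genes and 3 adjusted over the list alone; camera adjusted p = 0.0075, adjusted p = 0.28 with an estimated correlation), and not with age as a block (adjusted p = 0.26). Immediate early genes were higher and stem markers lower (camera adjusted p = 0.0043 and 0.035; adjusted p = 0.66 for each with an estimated correlation; 0 genes adjusted over the list alone). With age as a block, cell cycle and Wnt genes were also called lower (adjusted p = 0.0059 and 0.021; adjusted p = 0.65 for each with the block and an estimated correlation), with 0 of 12 and 0 of 14 genes passing over all genes or adjusted over the list alone without the block.

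**Figure D4:**
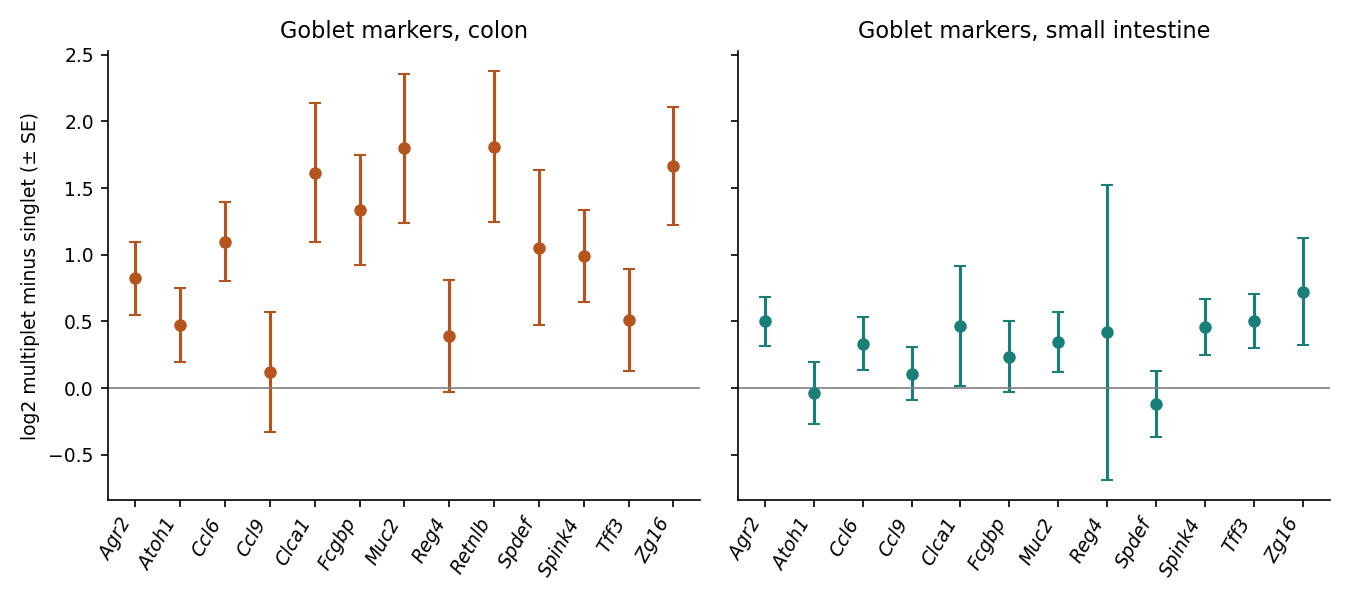
Bars give the log2 difference of multiplets minus singlets ± SE for each goblet marker, 13 in colon and 12 in small intestine. The colon median is 1.05 and the small intestinal median 0.38, and no single gene passed over all genes in either tissue.

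In the small intestine the same comparison had 3 ages on each side. Agr2 had 840.4 ± 185 CPM in multiplets and 594 ± 9.85 in singlets (log2 0.50, SE 0.18, edgeR adjusted p = 1). Muc2 had 1401 ± 344 CPM against 1105 ± 182 (log2 0.34, SE 0.22), and Lyz1 (chromosome 10, 117287797 to 117292868, minus strand) 611 ± 408 against 332 ± 298 (log2 0.88, SE 0.84). No gene of 13847 passed in edgeR, where 80 had an unadjusted p under 0.05, and DESeq2 called 0. Camera called 7 of 26 lists higher in multiplets, none with an estimated correlation, and in each 0 genes passed over all genes or adjusted over the list alone. These were goblet markers (median log2 0.38, camera adjusted p = 7.6e-06, adjusted p = 0.76 with an estimated correlation), immediate early genes (0.41, 7.6e-06, and 0.76), mucus (0.40, 0.00042, and 0.76), Paneth markers (0.86, 0.00054, and 0.86), antimicrobial genes (0.79, 0.00054, and 0.76), bile acid handling (0.81, 0.020, and 0.78) and B markers (1.18, 0.023, and 0.76). With age as a block 15 lists were called. Tuft markers (median log2 -1.72, adjusted p = 1.7e-18), Wnt genes (3.9e-08), stem markers (2.5e-07) and enteroendocrine markers (2.8e-05) were added as lower, and enterocyte markers (4.9e-06), colonocyte markers (0.00012), nutrient transport (0.00021) and lipid absorption (0.0012) as higher. With the block and an estimated correlation none of these 8 held (adjusted p from 0.31 to 0.53), and without the block no member of them passed over all genes or adjusted over the list alone. For enteroendocrine markers the median log2 was -0.61 while camera without the block pointed upward (adjusted p = 0.72).

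The difference between the tissues in this contrast was tested as an interaction. Goblet markers were raised less in small intestinal than in colon multiplets (median log2 of the difference -0.61, camera adjusted p = 0.0017, adjusted p = 0.95 with an estimated correlation, 0.0055 with age as a block). Mucus genes differed in the same direction (median log2 -0.76, camera adjusted p = 0.0017, adjusted p = 0.95 with an estimated correlation, 0.0021 with age as a block). No gene of 15283 passed in edgeR, none of either list adjusted over the list alone, 450 genes had an unadjusted p under 0.05, and DESeq2 called 16. With age as a block 8 lists were called in place of 2, adding lymphocyte markers (adjusted p = 2.1e-08) and tuft markers (2.1e-06) as lower in the small intestinal contrast, and cell cycle and the same cycling genes (0.00070), bile acid handling (0.0077) and colonocyte markers (0.030) as higher. With the block and an estimated correlation none of these held (adjusted p from 0.68 to 0.69), and without the block no member passed over all genes, and 5 of 8 lymphocyte genes did adjusted over the list alone.

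Classes per multiplet were read by fitting each well as a mixture of the class profiles of singlets. Goblet-like RNA was called in 60.9% of all colon multiplets (95% Clopper-Pearson interval 58.5 to 63.3, which covers the counting of wells and not the spread between ages). By age the share ran from 33.3% (age 207) to 89.8% (age 269). It was called in 30.1% of colon singlets fitted alike, but 1254 of the multiplets carry no age and their plates held no singlets. In small intestine it was called in 22.7% of multiplets and 13.9% of singlets. Stem-like RNA was called in 24.7% of colon multiplets and 40.9% of colon singlets, and cycling RNA in 53.1% of small intestinal multiplets and 34.9% of singlets. Paneth-like RNA was called in 7.49% of small intestinal multiplets and 2.88% of singlets. At least 2 classes were called in 66.2% ± 0.322 of small intestinal multiplets over 3 ages against 39.3% ± 2.40 of singlets. In colon the share was 55.3% ± 22.6 of multiplets against 36.5% ± 9.20 of singlets over 5 ages, lowest at age 453 with 28.6%, and 67.7% in multiplets without an age. The share in singlets is the background of the method, and none of these shares was tested.

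Pairs of classes found in the same multiplet were compared with 1000 shuffles that kept class totals and the number of classes per well within each age. Paneth and stem classes, neighbours at the base of small intestinal crypts, shared 22 of 414 small intestinal multiplets, or 5.31% (95% Clopper-Pearson interval 3.36 to 7.94), where 2 of 1075 singlets fitted alike (0.186%) carried the pair. The pair was found 15 times against 7.96 expected at age 453 and 7 times against 2.16 at age 492, a mean log2 of 1.19 ± 0.44 over 2 ages (exact sign-flip p = 0.50, the smallest possible). Absorptive and stem classes, which lie at opposite ends of the crypt axis, shared fewer small intestinal multiplets than expected (log2 -2.53 ± 0.60, below 0 in 3 of 3 ages, exact sign-flip p = 0.25, the smallest possible). At ages 304 and 453 no well held the pair, against 2.83 and 3.49 expected, so the 0.5 added to each number limits these values. In colon that pair stood at -0.87 ± 1.25 over 5 ages (exact sign-flip p = 0.25), and at 7 wells against 43.3 expected in multiplets without an age. With the unnamed clusters left out of the reference, an alternative chosen after the results were seen, the mean over the colon ages turned to 0.70. Absorptive and goblet classes shared fewer colon multiplets than expected in 5 of 5 ages (log2 -1.11 ± 0.78, exact sign-flip p = 0.062, the smallest possible), with 54 against 124.9 in those without an age. In small intestine the same pair stood at 0.29 ± 0.87, and the difference between the tissues was 1.40 (exact permutation p = 0.0357, adjusted p = 0.268 over 15 pairs). Cycling and goblet classes stood at 0.34 ± 0.12 in small intestine, above 0 in 3 of 3 ages, and at -0.0044 ± 0.30 in colon. Goblet with stem and cycling with stem lay within 1 SD of 0 in both tissues. They stood at -0.13 ± 0.48 and -0.03 ± 0.19 in small intestine, and at -0.27 ± 0.45 and -0.10 ± 0.49 in colon. In 400 random pairs of colon singlets goblet with stem gave -0.34, and still -0.080 with 80 of the 400 seeded as that pair. Random pairs drawn to match all colon multiplets gave 0.49 for cycling with stem. Closeness to 0 in colon is therefore no evidence that these pairs are absent. The colon multiplets without an age went the other way from the colon ages for goblet with stem (178 wells against 137.1 expected, log2 0.38). They lay above the ages for cycling with goblet (161 against 129.5, log2 0.31). Both values come from shuffles over all of these wells together. None of the 15 pairs differed between the tissues after adjustment.

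**Figure D5:**
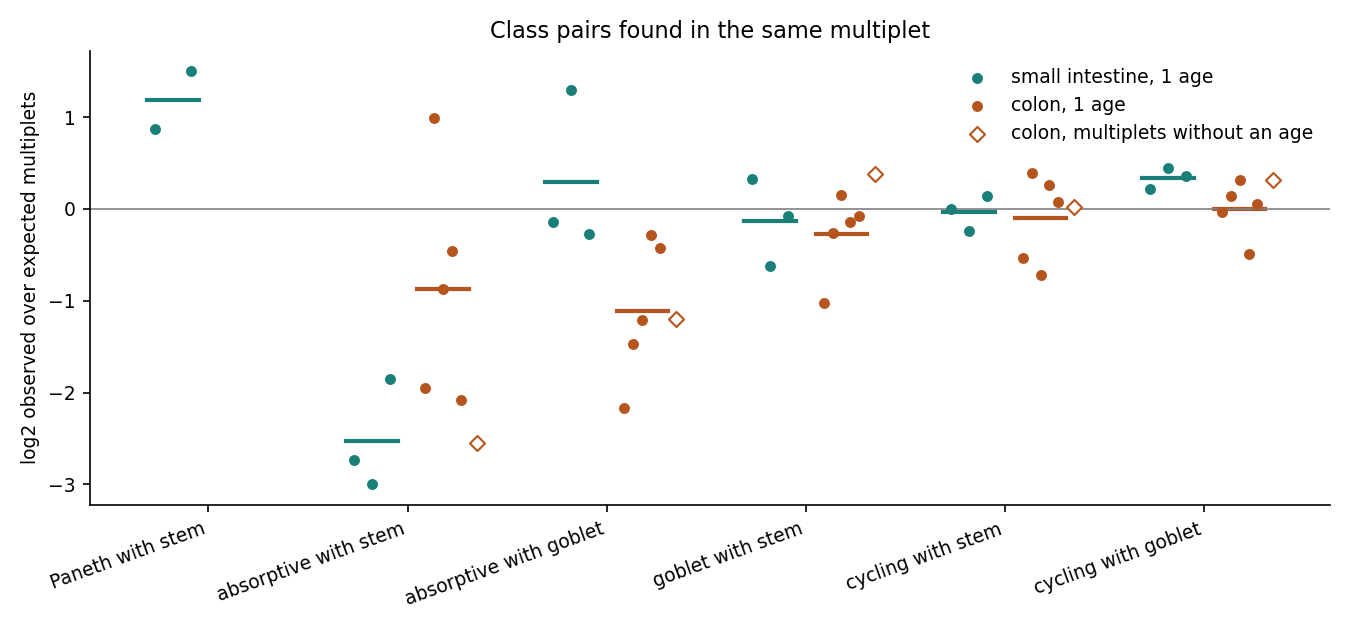
Each point is the log2 ratio of observed to expected multiplets that hold both classes in 1 age, bars mark the mean, and open diamonds stand for colon multiplets without an age. Absorptive with stem lies at a mean of -2.53 in small intestine and -0.87 in colon, and Paneth with stem at 1.19 over small intestinal ages 453 and 492.

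The spleen, an immune organ without epithelium, served as a further tissue in which cells were sorted through the same kind of gates, and its values carry no test. Of 1115 singlets, 41.1% were B cells, 22.5% T cells, 7.35% NK cells, 1.70% monocytes, 1.26% dendritic cells and 26.1% had no name. The B cell share ran from 3.42% to 62.5% over the plates. In 542 multiplets, B cell RNA was called in 57.6% and T cell RNA in 14.2%. Pairs were shuffled over all plates together, so the unlike make-up of the plates enters the expected numbers, and enrichment within plates was not measured. Dendritic cells and monocytes shared 21 multiplets against 2.40 expected (log2 2.89), where random pairs of singlets gave -0.51. Their profiles rest on 14 dendritic and 19 monocyte singlets, and the random pairs drew on the same few cells. NK and T cells shared 17 against 2.80 (log2 2.41), but random pairs of singlets gave a like 2.37. B and T cells shared 24 against 34.5 expected (log2 -0.52), and B cells and monocytes 3 against 23.6 (log2 -2.78).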

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

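The test against 2 random cells per multiplet was chosen only after the result was seen, and its bound was changed once its values were known. Named colon genes were screened for a single age far from the other 5, in 67 groups of 6 ages, where chance singles out about 1 in 20 groups. In all colon singlets Fut9 had 80.1 CPM at age 359, where the other ages ran from 20.1 to 42.5. In cycling colon singlets Fut9 again stood apart at age 359, with 147 CPM against 28.8 to 55.6. Cma1, a mast cell chymase gene, had 79.96 CPM in goblet-like colon singlets of age 359 against 2.31 to 27.7. At age 453, goblet-like colon singlets had 1.88 CPM of the membrane protease Tmprss13, against 38.4 to 50.6. Best2 was also low in goblet-like cells of age 453, at 112 CPM against 276 to 369. In none of these 5 does the age change the direction against the small intestine. Goblet markers and mucus genes were singled out because their multiplet to singlet difference was smaller in small intestine than in colon, by a median log2 of -0.61 and -0.76 in a camera test of the interaction; neither call held with an estimated correlation (adjusted p = 0.95 for each) or in fry, and no member of either list passed adjusted over the list alone.

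Goblet genes stood higher in colon multiplets than in colon singlets, by a median log2 of 1.05 over the 13 markers, none of which passed over all genes, and the camera call of the list was lost with an estimated correlation (adjusted p = 0.28) and in fry. A single deep age does not carry the camera call, since without each of the 5 multiplet ages in turn the highest camera adjusted p was 1.1e-08. At 4 of 5 ages goblet-like RNA was found over 10 points more often than 2 random sorted singlets would carry it. The shares were 89.8% against 73.1%, 68.6% against 20.9%, 85.7% against 64.4% and 80.3% against 60.1% at ages 269, 304, 453 and 492. This argues against 2 random cells drawn from the sorted singlets, but larger clumps were not tested. An unmarked CD24 gate may have set the singlet shares, so random pairing in the tissue is not excluded. Age 207 decides nothing: the difference there was -26.9 points (33.3% against 60.2%), but its multiplets resembled singlets, with 1.04 times their RNA on the same plate, 57.5 more genes, 41.7% against 41.4% with at least 2 classes and 33.3% against 36.9% with goblet-like RNA. At age 453 the share with at least 2 classes was no higher in multiplets either (28.6% against 29.8%), but they had 1.91 times the RNA and 85.7% against 40.3% with goblet-like RNA. As first written that test needed all 5 ages above and would have stayed undecided; it was then parted by age, with at least 1.1 times the RNA of singlets required. A larger RNA content of goblet cells cannot be told apart from a larger number of them. Goblet-like colon singlets had 1.33 times the counts per spike-in count of other named singlets (1.21 to 1.54 over 6 ages), between the bounds of 1.1 and 1.5 set beforehand. A tendency of colonic goblet cells to stay attached may add to the goblet excess, untested. In small intestine goblet-like singlets had 0.836 to 0.890 times the counts per spike-in count of other named singlets at ages 304, 453 and 492. Whether this accounts for the smaller goblet difference in small intestinal multiplets was not tested.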

How the results depend on the processing

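Chosen only after the results were seen were the fits over shared ages without a block, without age 453, without colon multiplets of ages 207 and 453, with the colon multiplets that have no age as a further sample, without the unnamed clusters, and minus random pairs of singlets. Of 4255 values of named genes under other settings, 3979 kept their direction and side of the threshold, 274 kept the direction only and 2 reversed: Mcm6 in absorptive singlets (log2 -0.72 in wells with at least 100000 counts and 1500 genes) and Fcgbp in small intestinal multiplets (-0.042 with wells scaled to the same total). Counts within 1.5 times the main one were found in 16 of 18 settings for all singlets, 13 of 16 for stem-like, 11 of 16 for cycling, 14 of 16 for goblet-like and 8 of 10 for absorptive singlets, 20 of 21 for colon multiplets, 15 of 15 for small intestinal multiplets and 25 of 26 for the interaction. With age as a replicate block the counts fell to 1250 for all singlets, 375 for stem-like, 452 for cycling and 745 for goblet-like singlets; over the same shared ages without a block they were 941, 416, 535 and 774, so fewer samples account for the drop. Pairing of the tissues by age was weak where seen. Same-aged samples correlated at 0.195, 0.148 and 0.0783 (all singlets, ages 304, 453 and 492), from -0.014 to 0.139 (stem-like), 0.058 to 0.092 (cycling) and 0.032 to 0.102 (goblet-like). Some but not all samples correlated best with their own age, so pairing of the tissues is neither shown nor excluded. DESeq2 called 1471 genes in stem-like, 1358 in cycling and 1966 in absorptive singlets, 13 in colon multiplets and 16 in the interaction; the cause was not tested. Leaving out 1 age gave 1549 to 2350 genes for all singlets, 603 to 912 for stem-like, 520 to 947 for cycling (520 without small intestinal age 304 and 561 without age 492), 1117 to 1424 for goblet-like and 658 to 871 for absorptive singlets, and 0 throughout for the multiplet comparisons in edgeR. Without small intestinal age 492 the absorptive fit called 658 genes, 31.8% of them higher in small intestine against 45.0%, and its lone small intestinal sample is assumed to vary like the others.

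With an estimated correlation the calls of lists dropped to 1 for all singlets, 8 for stem-like, 5 for cycling and 9 for goblet-like singlets. They dropped to 0 for absorptive singlets, colon multiplets, small intestinal multiplets and the interaction. That test widens the error of correlated genes, which does not fix how many calls are lost. In stem-like singlets 8 of 14 calls held, and in goblet-like singlets 9 of 14. The fry test called 11 lists for all singlets, 11 for stem-like, 10 for cycling, 15 for goblet-like and 3 for absorptive singlets, and 0 in colon multiplets, small intestinal multiplets and the interaction. With the block, 7 lists were called in colon multiplets in place of 5 (4 of them in both), 15 in small intestinal multiplets in place of 7 and 8 in the interaction in place of 2, and the paired colon difference of 1215 genes per well had an exact sign-flip p of 0.062. Class shares kept their direction in 106 of 116 settings, though the stem-like difference (main -13.5 points) was -29.2 and -7.42 at clustering resolutions 0.5 and 1.5. The difference in unnamed cells (main -1.23 points) was 1.88 with the block, 14.6 at clustering resolution 0.5, 7.50 in wells with at least 100000 counts, and -4.89 to 1.26 without 1 age. That in enteroendocrine-like cells ran from -1.52 to 0.341, and that in lymphocytes from -0.159 to 1.84, without 1 age. Counts per spike-in count kept their direction in 23 of 23 settings and genes per well in 25 of 25, of which 1 lost its side of the threshold.

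Mean classes per small intestinal multiplet (main 1.88) were 2.07 and 1.47 at presence thresholds of 0.10 and 0.25, 1.76 with a log2 fit, 1.85 and 1.91 with 20 and 100 genes per class, 1.93 with profiles of both tissues and 1.68 without unnamed clusters, and the threshold sets how many classes pass by construction. Pair values kept their direction in 109 of 130 settings within a tissue and 72 of 85 between tissues, and those that reversed lay near 0 or rested on few wells; the cause was not tested. Without 1 age, small intestinal absorptive with goblet ran from -0.21 to 0.58, cycling with stem from -0.12 to 0.073 and goblet with stem from -0.35 to 0.12, and in colon cycling with goblet from -0.084 to 0.12 and cycling with stem from -0.23 to 0.050. At a threshold of 0.25, small intestinal cycling with stem was 0.070, colon cycling with goblet 0.16 and colon cycling with stem 0.016; at 0.10 the last was 0.17. Small intestinal goblet with stem was 0.040 with the log2 fit and 0.10 with 100 genes. Colon cycling with goblet was 0.026 with 20 genes and 0.070 minus random pairs, and colon cycling with stem 0.24 with 100 genes and 0.087 with profiles of both tissues. Without unnamed clusters, small intestinal cycling with stem was 0.17, colon absorptive with stem 0.70, colon cycling with goblet 0.00061 and colon cycling with stem 0.11. Between tissues, cycling with stem (main 0.07) was -0.080 to 0.20 without 1 age, -0.41 at 0.10, -0.33 with the log2 fit, -0.19 and -0.32 with 20 and 100 genes and -1.01 with profiles of both tissues. Goblet with stem (main 0.14) was -0.10 with the block, -0.081 to 0.39 without 1 age, -1.19 at 0.25 and -0.075 with profiles of both tissues. Alternatives set beforehand that gave no value were leaving out mitochondrial genes (none are in the files), the ageless colon multiplets in the small intestinal comparison (they do not enter it), the block in absorptive singlets (1 shared age) and the Paneth share in the stricter well filter. Depth limits what 0 counts exclude: over all colon singlets the floor of 3 counts lay at 0.00594 CPM.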

Other observations

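The tests of Paneth with stem pairs, the counts of other splits and the list of hormone genes were chosen only after the results were seen. Enteroendocrine-like singlets, the hormone-secreting cells of the lining, numbered 24 in small intestine and 40 in colon, too few per age for a test. Gip, the incretin of the upper gut, had 1086 CPM and counts in 5 of 24 small intestinal cells, and no count in 40 colon cells, where 3 counts would be 0.501 CPM. Cck, which empties the gallbladder, had 1374 CPM (13 of 24 cells) in small intestine and 164 CPM (7 of 40) in colon. Ghrl, ghrelin, had 649 CPM (5 of 24) and 17.02 CPM (4 of 40), and Tac1, a tachykinin, 2934 CPM (18 of 24) and 467 CPM (13 of 40). In colon, Insl5, a hormone of distal L cells, had 325 CPM (5 of 40 cells, 0 to 1774 CPM over the ages). Sst, somatostatin, had 552 CPM there (5 of 40, 0 to 1193) and Nts, neurotensin, 256 CPM (3 of 40, 0 to 928). None of the 3 had a count in small intestinal cells. Pyy, a satiety peptide, had 704 CPM in colon (9 of 40, 0 to 2797 over the ages) and 12.1 CPM in small intestine, from 1 cell. Gcg, the glucagon precursor, had 1412 CPM in small intestine and 1286 CPM in colon, the latter from 6 of 40 cells and from 0 to 6102 CPM over the 5 ages with at least 3 cells. Sct had 1026 CPM in small intestine and 582 CPM in colon (56.4 to 1634 over the ages). Tph1, which makes serotonin, had 2492 CPM in small intestine and 4086 CPM in colon (374 to 7300 over the ages), and Vip had no count in either.

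Enteroendocrine-like and stem-like classes shared 7 of 414 small intestinal multiplets, a mean log2 of 0.59 ± 0.74 over 3 ages in shuffles within an age. They shared 7 of 1254 colon multiplets without an age against 3.16 expected in shuffles over all of them (log2 1.04), where the mean over 4 colon ages was 0.35 ± 0.75. In the same colon multiplets, goblet and stem classes shared 178 against 137.1 expected (log2 0.38) and cycling and goblet classes 161 against 129.5 (log2 0.31), while the means over the 5 colon ages were -0.27 ± 0.45 and -0.0044 ± 0.30. These wells had a median of 6694.5 genes each.

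Ages 304 and 359 held few cells of the rare secretory classes. No tuft-like cell was found among 225 small intestinal singlets of age 304, 424 colon singlets of age 304 or 643 colon singlets of age 359, no Paneth-like or enteroendocrine-like cell in small intestine at age 304, and enteroendocrine-like cells made up 0.472% and 0.778% of colon singlets at ages 304 and 359. Shallower wells are argued against, since the markers of these classes, summed over all wells, stood at 0.117, 0.115 and 0.219 of the median of the other ages (the decisive highest ratio being 0.219), where no other age lay below 0.811 in small intestine or 0.553 in colon. The bounds set beforehand were 0.1 and 0.5 and would have left this undecided; the rule was changed after the values were seen to a distance of more than 2 SD below the other ages. A CD24 gate drawn at the other ages only stays open and cannot be told apart from a difference between animals: Cd24a in stem-like singlets lay below each other age in 0 of 3 samples, which the bound set beforehand would have read as excluding the gate, but at colon age 304 (512 ± 34.5 CPM, SE) it exceeded the lowest other age (491 ± 37.6) by less than its error, a condition added after the values were seen. Stem-like Cd24a went the other way at small intestinal age 304 (738 ± 98.2 CPM against 613 and 600) and colon age 359 (658 ± 35.3 against a lowest of 491). Other classes go with such a gate in part. In goblet-like singlets Cd24a lay below each other age in all 3 samples (342 ± 57.1 CPM against 737 and 957 in small intestine, and 805 ± 108 and 978 ± 45.1 against 1172 to 1723 in colon). In cycling singlets it lay below each other age at age 304 of both tissues, but with overlapping errors. The values were 383 ± 44.6 against 423 ± 31.3 in small intestine and 347 ± 40.9 against 411 ± 47.5 in colon. At colon age 359 cycling singlets did not lie below (528 ± 58.7 against a lowest of 411).

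Paneth and stem classes shared 22 small intestinal multiplets, more than shuffles gave. Free Paneth RNA in wells stays undecided. The Paneth class was called in 0 of 224 stem-like singlets and in 22 of 141 multiplets with the stem class (15.6%). But the stem profile was made from these same singlets, and singlets with much Paneth RNA may have clustered elsewhere, so a result near 0 was likely beforehand. Similar profiles called together did not reach the observed value in random pairs of singlets, which gave at most 0.36 of the log2 enrichment. The 22 wells lay 3.04 SD above the 12.8 expected with random pairs, a second condition added after the values were seen. But each pair mixed 2 singlets in equal parts, drawn from the same singlets that made the profiles, with 28 Paneth-like cells. Such pairs may understate joint calls in real clumps, so similar profiles are not excluded as a cause. Attachment of Paneth cells to stem cells at the crypt base may account for the excess over random pairs. It is a hypothesis found and tested on the same data, in 2 ages. A sort gate on CD24, which would also let clumps with a Paneth cell through, was not tested.

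Other splits of the samples were counted for each comparison. Of the 84 splits of the 9 samples by tissue and age into 3 and 6, only the real one gave as many genes in 4 comparisons. These were all singlets (2291 genes, highest other split 1), stem-like (834, highest other 1), cycling (870, highest other 0) and goblet-like singlets (1480, highest other 0). A random split of these samples is thus an unlikely source of such counts. Every other split mixes the tissues, and plate goes with tissue, so the splits say nothing about plates. In the class comparisons the clusters were already nearly parted by tissue on the same data. For colon multiplets the real split gave 0 genes in edgeR (931 at an unadjusted p under 0.05, 13 in DESeq2), a count that any split reaches, so that all 100 of the splits drawn from 462 gave as many says nothing about chance; the splits also break the pairing by age. The highest, 346 genes, set multiplets and singlets of ages 207 and 304 and singlets of age 359 against the rest. This points to a structure of the samples that goes with age and with plate, which cannot be told apart here. The counts are as empty for small intestinal multiplets, where all 10 of 10 splits reached the real 0 in edgeR (80 unadjusted, 0 in DESeq2; highest other 4) and would be too few for a share under 0.05, and for the interaction, where 84 of 84 splits reached the real 0 (450 unadjusted, 16 in DESeq2; highest other 3).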
